A study of Gallus gallus with 40 samples.

How the data were processed

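Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out by the submitters in primary mesenchymal cells taken from chicken limb buds, infected with an RCASBP virus and kept in culture for 6 days, per the labels' protocols. RCASBP is a replication-competent avian retroviral vector that carries a chosen gene into dividing chicken cells. Each infection carried a FLAG-tagged HOX gene or an HA-tagged CTCF gene. HOX and CTCF proteins were precipitated through their tags. RAD21, a subunit of cohesin, was precipitated with an antibody against the protein itself in cells infected with HA-CTCF. The labels list 40 libraries, of which 21 are ChIP and 19 are input chromatin. Each factor has 2 ChIP libraries, except HOXA13 with 1. RAD21 has no input group of its own in the labels.

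The submitters' processing notes name BWA 0.5.9, SAMtools 0.1.18, Picard 1.56, MACS2 2.0.10.20120913, bedtools without a version, and the chicken genome build galGal4. They give no role or order for these tools, and the parameters are not given in the sources used here. The authors deposited 20 peak lists, 11 with the peaks of a factor and 9 named for the overlap of a HOX factor with CTCF. Every interval in the 11 factor lists is 301 bp wide, which means that the deposited intervals carry a fixed width and not the extent of each peak. Each peak has a deposited score in its last column. The files have no header and name neither the statistic nor the log base of that score, so it was used only to rank or compare peaks within a list. The lowest score ranged from 7.99 for HOXA10 to 28.4 for HOXD11. Peak names carry running numbers up to between 197195 and 650802, far above the list lengths, so each list holds part of a longer numbered set whose selection rule is not given in the sources used here. How far that rule set the list lengths, or the share of weak sites in a list, is unknown.

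There is 1 list per factor and no value per library. Whether the replicates were pooled before or after peak calling is not given in the sources used here. Replicate spread could not be measured, the factor was the unit of every test, and the p-values measure consistency across factors. All HOX lists were set against the same CTCF and RAD21 lists, so the lists are not fully independent in those tests. Read depth is unknown, because the lists hold no read counts. Exact Clopper-Pearson intervals at 95% are given for shares of peaks and cover counting error only.

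A peak was counted as overlapping another list when they shared 1 bp or more. Peaks of the 9 HOX lists were merged into regions wherever they overlapped, and the Jaccard index of a pair of lists is the number of regions in both divided by the number in either. Overlap by chance was taken as the mean of 1000 random placements of each list on the same chromosomes. For pairs of HOX lists it was computed from the peak counts and the chromosome spans, without placements. Similarity tests permuted the names of the 9 HOX lists in all 362880 orders. Paired differences were tested with all 512 sign patterns, and group differences in CTCF share with all 126 splits. These tests were exact and two-sided, and their 12 p-values were adjusted together by the Benjamini-Hochberg method. Lists were clustered by average linkage on 1 minus the Jaccard index and divided into 2 groups, with no p for groups formed from the same values. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. On simulated lists of 20000 peaks with planted CTCF shares of 5% and 25%, the recovered shares after removal of chance overlap were 5.15% and 25.1%. The CTCF shares reported below have no such correction and include chance overlap. A planted Jaccard index of 0.5 came out at 0.502. The similarity test called 5.0% of 100 simulated sets without an effect and 100.0% of 50 sets with a planted shift of 0.15. Pair values in these sets were independent, every paralog pair was shifted alike, and the shift was larger than the 0.107 observed. The runs checked the code and do not give the power or error rate for these data.

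Alternatives were the upper 50% of each list by score, 12540 best-scoring peaks of every HOX list, an overlap of at least 50% of each peak, the upper 50% of the CTCF list, local shifts of 5 to 50 kb as the chance level, complete linkage, a log2 ratio of observed to random overlap, CTCF peaks matched by score decile, and leaving out HOX lists. The tests, these alternatives and the rule for named regions were fixed before the data were examined. The rule takes the 5 regions with the best mean rank within their lists from each of 4 sets, which are all 9 HOX lists, each of the 2 clustered groups without the other, and CTCF with RAD21 and the most HOX lists. Added after seeing the data were the division into 3 groups, regions without CTCF, an overlap of at least 100 bp, the comparison over 6 lists, the tests of CTCF overlap, RAD21 and score without HOXA13, and the omission of other lists in tests other than that of paralog pairs. For 301 bp intervals, an overlap of at least 50% and centres within 150 bp are the same criterion, which was run once.

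A gene annotation or sequence of galGal4 was not used here. The gene table at hand was for another assembly, whose coordinates cannot be set beside these. The planned analyses of location relative to genes, of peaks near fixed gene lists and of sequence motifs, 3 in number, were therefore not run, and regions are given by galGal4 coordinates, counted from 1, without gene names.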

Results

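Binding sites of 9 posterior HOX proteins, tagged and delivered by virus, were mapped along with those of CTCF and RAD21 in cultured chicken limb bud mesenchymal cells. Each HOX protein and CTCF was delivered in a separate infection. Overlap between their lists therefore does not show that the proteins were bound together in the same cells. RAD21 was mapped in cells infected with CTCF, so no RAD21 value comes from cells with a delivered HOX protein. HOX proteins are homeodomain transcription factors that pattern the body axis and the limb, and genes of the HOXA and HOXD clusters that carry the same number are paralogs. CTCF is a zinc finger protein that binds insulators and the borders of chromatin domains, where it often meets cohesin. The HOX lists came from 17 ChIP libraries with 17 inputs, with 1 ChIP library for HOXA13 and 2 for each other factor. Together the lists of HOXA9, HOXA10, HOXA11, HOXA13, HOXD9, HOXD10, HOXD11, HOXD12 and HOXD13 held 199847 peaks. The shortest was HOXA13 with 12540 peaks and the longest HOXA10 with 28572. The CTCF list had 22357 peaks and the RAD21 list 17589. Each factor had a single list, so no value has a replicate error, each SD is across lists or pairs of lists, and the read depth behind the lists is unknown.

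The first comparison asked how far the HOX proteins occupied the same sites. The HOX peaks merged into 76333 regions, of which 42335 (55.5%) were in 2 or more lists, 13471 in at least 5 and 826 in all 9. HOXD13 and HOXA13 had the highest shares of regions found in no other HOX list, 33.4% and 31.9%, followed by HOXA10 with 20.9% and HOXD9 with 19.4%. The lowest share was that of HOXD12, 7.54%. In all 36 pairs of lists the number of overlapping peaks was 15.7 to 43.9 times that expected from peak counts and chromosome spans. Of the regions in all 9 lists, the 5 that ranked highest were on galGal4 chromosome 5 at 42746818 to 42747184, chromosome 24 at 4506906 to 4507306, chromosome 15 at 11124704 to 11125025 and at 4625212 to 4625608, and chromosome 11 at 16546408 to 16547244. The chromosome 15 region at 11124704 overlapped a CTCF peak, the chromosome 11 region overlapped a RAD21 peak, and the other 3 overlapped neither.

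Paralogs shared more sites than other pairs of HOX proteins. HOXA11 and HOXD11 had the highest Jaccard index, 0.503, and HOXA10 and HOXD10 the next, 0.443. HOXA9 and HOXD9 reached 0.337, which was below the 0.392 of HOXA9 and HOXD10. HOXA13 and HOXD13, the paralogs of the most posterior group, reached only 0.107, below the median of 0.255 over the 36 pairs. The mean Jaccard index was 0.348 ± 0.174 (SD) over the 4 paralog pairs and 0.240 ± 0.079 (SD) over the 32 other pairs, a difference of 0.107 (exact permutation test, p = 0.00847, adjusted p = 0.0169). The difference rested on the pairs of groups 10 and 11. It was 0.0501 without HOXD11 (exact permutation p = 0.233), 0.0625 without HOXA11 (exact permutation p = 0.143), 0.0758 without HOXA10 (exact permutation p = 0.0952), 0.0856 without HOXD10 (exact permutation p = 0.0571) and 0.179 without HOXD13 (exact permutation p = 0.00238).

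Taken over all 9 lists, similarity fell with the distance between the numbers of the genes. Over the 36 pairs, the Jaccard index correlated with the difference in paralog number at r = -0.503 (permutation of the list names, p = 0.00141, adjusted p = 0.0117) and rho = -0.453 (p = 0.00538 by permutation, adjusted p = 0.0129). Leaving out each HOX list in turn gave r between -0.617 and -0.410, each past the threshold, but no run left out both HOXA13 and HOXD13. These lists had the lowest mean indices with the other 8 lists, 0.133 and 0.197. Every pair of the greatest distance holds HOXA13 or HOXD13. The most distant pairs without them, HOXA9 with HOXD12 and HOXD9 with HOXD12, had indices of 0.327 and 0.281, above the median of 0.255. A graded fall among groups 9 to 12 is therefore not shown. Membership in the HOXA or HOXD cluster was not associated with sharing at the threshold. Pairs within a cluster had a mean index of 0.240 ± 0.072 (SD, 16 pairs) and pairs across clusters 0.262 ± 0.113 (SD, 20 pairs; exact permutation test, p = 0.413, adjusted p = 0.495). The difference was -0.0214, and without HOXA11 it was 0.00875 (exact permutation p = 0.857). Every paralog pair lies across clusters, so this comparison does not separate cluster from paralogy.

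**Figure D1:**
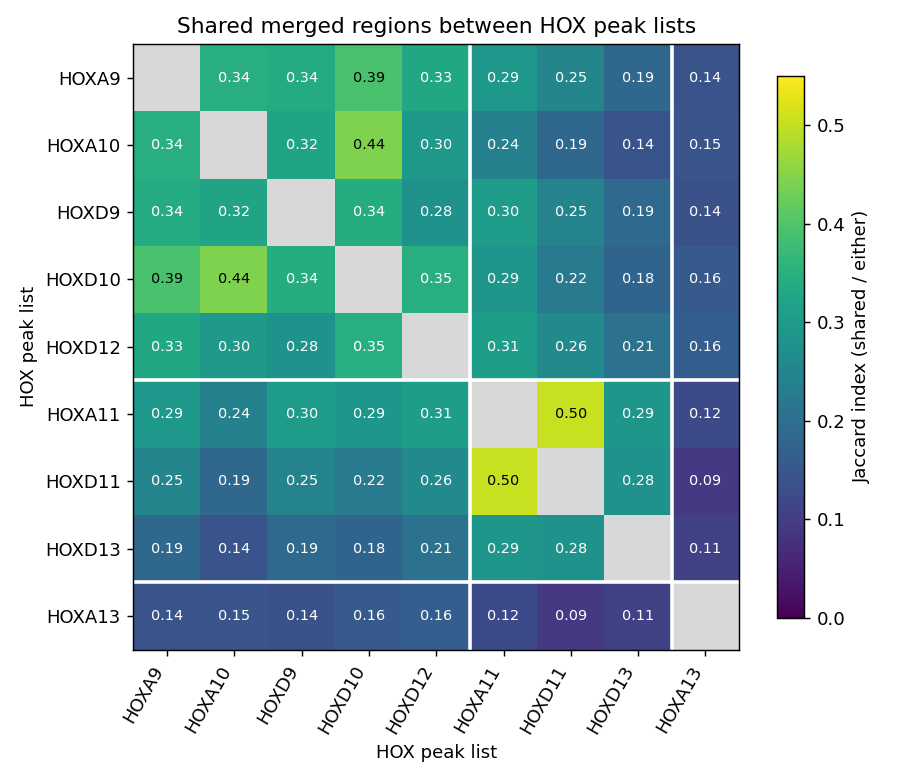
Jaccard index for each pair of the 9 HOX peak lists on both axes, with colour and printed values giving regions in both lists divided by regions in either. White lines separate 3 clustered groups, and the index runs from 0.091 for HOXA13 with HOXD11 to 0.503 for HOXA11 with HOXD11.

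The series title names a subgrouping of these proteins, and the lists were clustered by shared regions. Divided into 2 groups, the lists split into HOXA13 and the 8 others, with a mean silhouette of 0.156. The mean index was 0.286 ± 0.081 (SD) for the 28 pairs within the larger group and 0.133 ± 0.025 (SD) for the 8 pairs with HOXA13. Divided into 3 groups, a number chosen after seeing the data, HOXA9, HOXA10, HOXD9, HOXD10 and HOXD12 formed a group, HOXA11, HOXD11 and HOXD13 another, and HOXA13 stood alone (mean silhouette 0.133). The mean index was 0.347 ± 0.065 (SD) over the 13 pairs within these groups and 0.199 ± 0.065 (SD) over the 23 pairs between them. HOXA13 is also the factor with 1 ChIP library and the shortest list. Among regions of HOXA13 without another HOX protein, the highest ranked were on chromosome 4 at 90177953 to 90178253, chromosome 20 at 4204135 to 4204435, chromosome 23 at 396303 to 396603, and chromosome 4 at 90159267 to 90159567 and at 1603392 to 1603692. The chromosome 20 region overlapped both a CTCF and a RAD21 peak. Among regions of the 8 others without HOXA13, the highest ranked were on chromosome 21 at 4576571 to 4576925, chromosome 5 at 44958212 to 44958543 and at 9317578 to 9317971, chromosome 6 at 7310396 to 7310734 and chromosome 2 at 134643830 to 134644299. The chromosome 5 region at 9317578 overlapped a RAD21 peak.

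HOX peaks lay at CTCF peaks far more often than randomly placed peaks, to an extent that differed widely between the proteins. HOXA10 overlapped CTCF at 25.2% of its peaks (95% exact interval 24.7 to 25.7) and HOXA13 at 24.9% (24.2 to 25.7). The shares were 23.1% for HOXD10, 21.7% for HOXA9, 21.3% for HOXD12 and 16.7% for HOXD9. They were lower for HOXA11 with 8.72% (8.39 to 9.06), HOXD11 with 5.03% (4.75 to 5.33) and HOXD13 with 3.77% (3.52 to 4.02). Random placement gave 1.34% to 1.66%. The shares were 2.81 to 16.7 times the random level, and the mean log2 ratio was 3.25 ± 0.99 (SD, n = 9 lists), above 0 in 9 of 9 (exact sign-flip permutation test, p = 0.00391, the smallest it can give, adjusted p = 0.0117). Random placement takes no account of open chromatin. HOX peaks also overlapped other HOX lists, and RAD21 peaks without CTCF, well above random levels. Hence this test cannot show an association particular to CTCF.

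**Figure D2:**
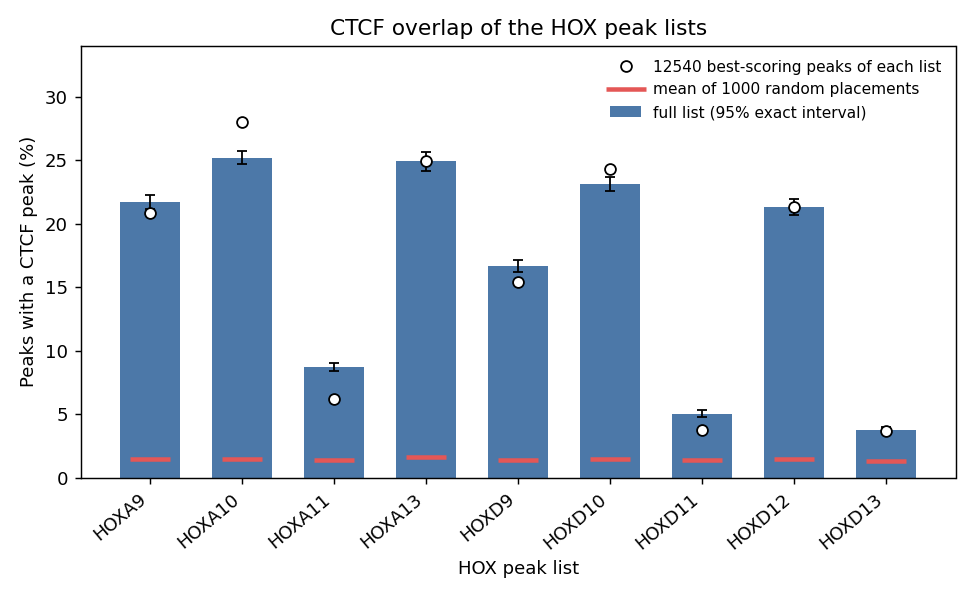
Percentage of peaks in each HOX list that overlap a CTCF peak, with bars for the full lists, error bars for 95% exact intervals, open circles for the 12540 best-scoring peaks and red marks for the mean of 1000 random placements. HOXA11, HOXD11 and HOXD13 lie between 3.77% and 8.72% and the 6 other lists between 16.7% and 25.2%.

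The 3 lists with the lowest CTCF shares were the 3 that clustered together by shared HOX regions. Regions bound by HOXA11, HOXD11 and HOXD13 and no other HOX protein, 1466 in number, overlapped CTCF at 0.341% (95% exact interval 0.111 to 0.794). Regions bound by HOXA9, HOXA10, HOXD9, HOXD10 and HOXD12 and no other, 466 in number, overlapped CTCF at 52.8% (48.1 to 57.4). For the 826 regions with all 9 proteins the share was 18.2% (15.6 to 21.0). These sets were chosen after seeing the data and their difference was not tested. Groups taken from the gene names did not differ at the threshold. The mean share was 20.1% ± 7.8 (SD, n = 4) for HOXA and 14.0% ± 9.1 (SD, n = 5) for HOXD lists (exact permutation test, p = 0.270, adjusted p = 0.360). It was 21.7% ± 3.6 (SD, n = 4) for groups 9 and 10 and 12.8% ± 9.7 (SD, n = 5) for groups 11 to 13 (exact permutation test, p = 0.127, adjusted p = 0.218). The planned correlation of CTCF share with list length over all 9 lists did not pass the threshold (exact permutation p = 0.498 for Pearson and 0.982 for Spearman, adjusted p = 0.543 and 0.982), and its coefficients are not given because the shares fell into 2 sets. Over the 6 lists outside the HOXA11, HOXD11 and HOXD13 group the correlation was r = -0.215 (exact permutation p = 0.692) and rho = 0.086 (exact permutation p = 0.919), and without the 2 lists farthest from the median length r was -0.462 (exact permutation p = 0.583).

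At shared sites, HOX and CTCF peak centres lay close together. The median distance between centres was 32 to 51 bp for 8 lists and 84.5 bp for HOXD13. Between 49.8% (HOXD11) and 66.0% (HOXD10) of the CTCF-overlapping peaks had centres within 50 bp of a CTCF centre, and 33.9% for HOXD13, where an even spread over the possible distances would give 16.8%. Chance overlaps would spread evenly and weigh most in HOXD13, whose CTCF share was only 2.81 times the random level, which lowers its value. RAD21 centres were closer still, with a median of 25 bp and 80.5% within 50 bp.

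**Figure D3:**
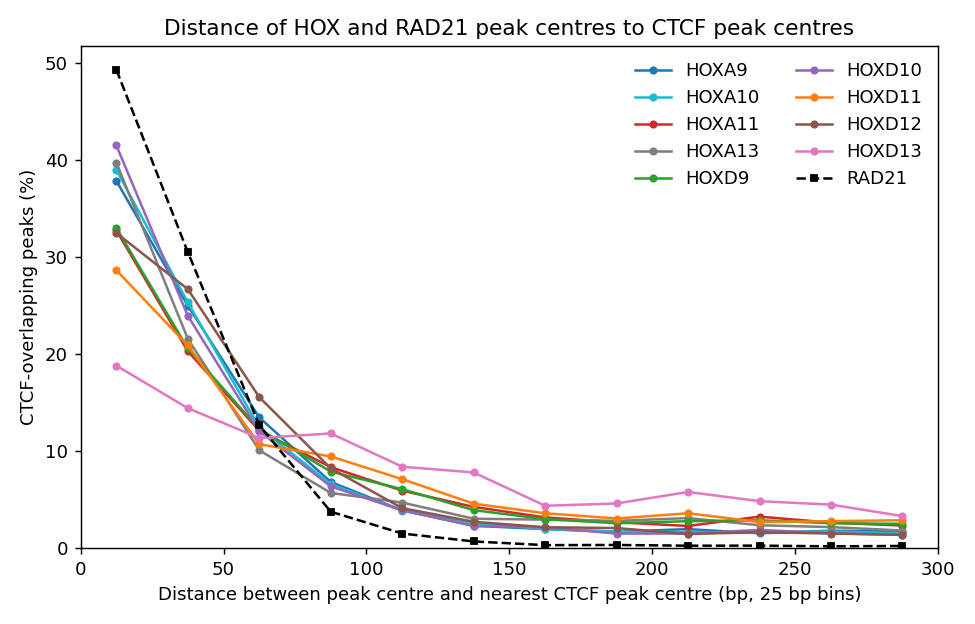
Percentage of CTCF-overlapping peaks by distance in bp from the peak centre to the nearest CTCF centre in 25 bp bins, with a solid line for each HOX list and a dashed line for RAD21. All lists peak in the first bin, and HOXD13 has the flattest curve with 33.9% within 50 bp.

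RAD21 overlapped HOX peaks mainly where CTCF was present. CTCF and RAD21 overlapped at 53.2% of CTCF peaks and 67.5% of RAD21 peaks, 45.3 and 45.4 times the random level. Among HOX peaks with CTCF, RAD21 was found at 58.1% (HOXA13) to 72.5% (HOXD12), and among HOX peaks without CTCF at 1.51% (HOXD13) to 5.44% (HOXD12). The difference was 61.4 ± 4.4 percentage points (SD, n = 9 lists), higher with CTCF in 9 of 9 lists. Because CTCF and RAD21 share so many sites, peaks divided by CTCF overlap would differ in this way whatever the HOX protein, so the planned test of this difference against 0 is not used as evidence about HOX proteins.

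CTCF peaks that overlapped a HOX peak had RAD21 more often than those that did not. The share with RAD21 was 58.4% (HOXA13) to 72.8% (HOXD12) at CTCF peaks that overlapped the HOX list and 46.7% (HOXA10) to 52.8% (HOXD13) at the others. RAD21 was mapped without a delivered HOX protein, so these values compare sites and not cells with and without it. The difference was 14.8 ± 6.5 percentage points (SD, n = 9 lists), positive in 9 of 9 (exact sign-flip permutation test, p = 0.00391, adjusted p = 0.0117). All 9 lists were set against the same CTCF and RAD21 lists, so the 9 differences are not independent. With CTCF peaks matched by score decile, the difference was 10.3 points (exact permutation p = 0.00781). Under that matching it ranged up to 17.9 points for HOXD12, fell to 1.33 points for HOXD9 and turned to -1.20 points for HOXA13.

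**Figure D4:**
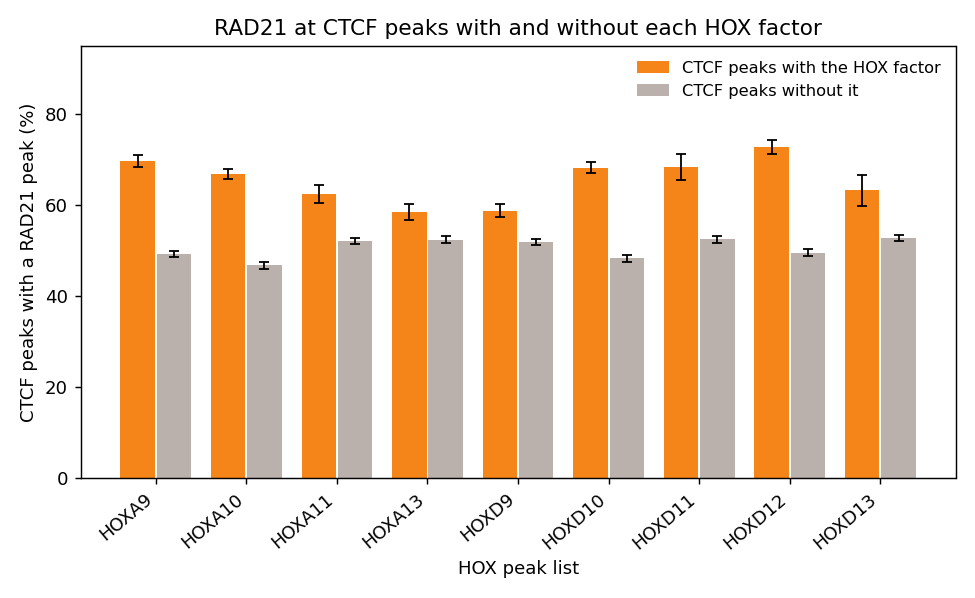
Percentage of CTCF peaks that overlap a RAD21 peak, for CTCF peaks with (orange) and without (grey) a peak of each HOX list, with 95% exact intervals as error bars. The orange bars run from 58.4% to 72.8% and the grey bars from 46.7% to 52.8%.

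Peaks of different HOX lists also fell on the same CTCF peaks. Of the CTCF peaks, 10825 (48.4%) overlapped at least 1 HOX list, and 2435 overlapped 5 or more, against 131.7 if the lists were independent, which is 18.5 times more. The HOX lists overlapped each other well above the random level over the whole genome, so this excess shows nothing particular to CTCF sites. RAD21 was present at 43.1% of CTCF peaks with no HOX protein, at 58.0% of those with 1, at 70.8% (95% exact interval 67.7 to 73.7) of those with 5 and at 62.5% (52.9 to 71.5) of the 112 with all 9. The median CTCF score also rose between these sets, from 25.3 with no HOX protein to 35.6 with 5, and was 31.7 with 9. The 5 regions that ranked highest among those in the CTCF, RAD21 and all 9 HOX lists were on chromosome 14 at 1495902 to 1496285, chromosome 17 at 2102399 to 2102737, chromosome 5 at 27625221 to 27625598, chromosome 27 at 2428342 to 2428826 and chromosome 15 at 4241850 to 4242176.

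HOX peaks with CTCF were not uniformly the stronger or the weaker ones. The median score percentile within its list differed most for HOXD11 (35.9 with CTCF and 50.8 without), HOXA11 (37.7 and 51.6) and, in the other direction, HOXA10 (54.9 and 48.2). Over the 9 lists the mean difference was -3.35 ± 7.38 percentile points (SD, n = 9), positive in 3 of 9 (exact sign-flip permutation test, p = 0.230, adjusted p = 0.346).

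The 9 deposited overlap lists held 29876 entries in all, from 696 for HOXD13 to 6728 for HOXA10. All were intervals of the CTCF list. An overlap of at least 100 bp between the full HOX and CTCF lists gave the same 29876 entries, with 0 missing and 0 extra, and an overlap of 1 bp gave 32489.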

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

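Of the tests below, that of CTCF sites for the microchromosomes was chosen only after the result was seen. Each of 9 measures was searched for a HOX list far from the 8 others, and 2 measures had such a list. Chance gives such a list in about 1 in 20 measures, and the lists are of different proteins, not replicates.

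HOXA13 had 32.5% of its peaks on microchromosomes, the small gene-dense chromosomes of birds (here 11 to 28), against 24.5% for the next list, HOXA10. The lowest share was 16.6% for HOXD13, and these chromosomes cover 17.1% of the span of the peaks. CTCF had 31.7% there, but CTCF sites did not account for the range among the HOX lists, which was 1.06 times as wide without the CTCF-overlapping peaks. List length did not account for it either, since with 12540 peaks from every list the range was 0.987 of the original. A bias toward GC-rich sequence could also differ between libraries and was not tested, as no galGal4 sequence was used here, so it stays open beside a binding preference of HOXA13.

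HOXD13 had 33.9% of its CTCF-overlapping peaks centred within 50 bp of a CTCF centre against 49.8% for the next lowest list, HOXD11, a gap of 0.495 of the whole range and barely past the limit for 9 values. Its CTCF share was 3.77% with a random level of 1.34%, so chance overlaps weigh more in it than in the other lists. Such overlaps lower the share within 50 bp and were not removed.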

How the results depend on the processing

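Leave-one-out values other than those for paralog pairs and some without HOXA13, the division into 3 groups, regions without CTCF and the 100 bp overlap were chosen after seeing the data. No paired analysis was possible because each factor has 1 list and no values per replicate, which also ruled out leaving out a replicate. Of 97 recomputed main results with a test, 92 kept their direction and side of the threshold; the RAD21 difference by CTCF overlap is left out of this count. The higher sharing of paralogs ranged from 0.0501 to 0.179 when each HOX list was left out in turn, with p past 0.05 in 4 of the 9 runs; it was 0.0758 without HOXA10, 0.0625 without HOXA11, 0.0856 without HOXD10 and 0.0501 without HOXD11. Each such run leaves fewer pairs. The difference between pairs within and across clusters, not past the threshold in any run, ranged from -0.0413 to 0.00875 and changed sign without HOXA11 only. Every paralog pair is a pair across clusters. Leaving out HOXA11 removes the paralog pair with the highest index, but leaving out HOXD11 removes the same pair and gave -0.0267. The cause of the change in sign was not tested. The 2 groups of lists and the 3 groups had the same members under 6 settings, and dividing into 3 in place of 2 left 6 of 9 lists in matching groups. Of the deposited overlap entries, 277 coincided with HOX intervals and 0 were intersections shorter than a peak. The CTCF ratio to the random level stayed above 0 on the log2 scale, between 3.02 with local shifts and 4.003 with an overlap of at least 50% of each peak. Of 45 recomputed CTCF shares of single lists, 36 were lower and 5 higher than the reported interval and 4 lay within it. The alternative limited to numbered and sex chromosomes changes nothing, since the lists hold no other sequence, and was not run; nor were those of the 3 analyses that need a galGal4 genome or annotation. The unknown depth and the unknown rule by which each list was selected limit every comparison of list lengths and shares.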

Other observations

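The 4 tests of the split in CTCF shares, the tests of list length and of the strongest HOXA13 peaks by target list, and the correlation with microchromosome share were chosen after the results had been seen.

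RAD21 peaks without CTCF also overlapped HOX peaks. Of 5710 RAD21 peaks without a CTCF peak, 33.7% (95% exact interval 32.5 to 34.9) overlapped at least 1 HOX list, where random placement gave 4.9998%. Among single lists the share ran from 5.50% for HOXD13 to 18.8% for HOXA10. Of the 11879 RAD21 peaks with CTCF, 58.3% (57.4 to 59.2) overlapped a HOX list, with a random level of 5.21%, and the shares of single lists ran from 4.55% for HOXD13 to 40.5% for HOXA10. Both random levels are for overlap with any HOX list. They are not the chance level of a single list, which would be lower and is not given here.

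Density along the chromosomes differed between CTCF and cohesin. CTCF had 41.3 peaks per Mb on microchromosomes and 17.2 on chromosomes 1 to 5, a ratio of 2.40. The ratio was 1.53 for RAD21, 2.51 for HOXA13, 1.00 for HOXD11 and 0.935 for HOXD13. RAD21 peaks without CTCF had 17.02% on microchromosomes, against 23.6% of all RAD21 peaks. Of regions with HOXA13 and no other HOX protein, 33.4% were on microchromosomes, and of regions with HOXA11, HOXD11 and HOXD13 alone 12.7%. HOXA11, HOXD11 and HOXD13, the lists with the lowest CTCF shares, also had the lowest microchromosome shares, at most 19.1% against at least 20.5% in the 6 others, and at most 18.7% against at least 19.4% without CTCF-overlapping peaks. Over the 6 others, CTCF share and the microchromosome share of peaks without CTCF gave r = 0.670 (exact permutation p = 0.186, adjusted p = 0.186) and rho = 0.886 (exact permutation p = 0.0333, adjusted p = 0.0667 over these 2 relations), and r = 0.887 without the 2 lists farthest from the median CTCF share (exact permutation p = 0.125).

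The CTCF shares separated HOXA11, HOXD11 and HOXD13 from the 6 other lists by 7.93 points. The microchromosome shares also put these 3 lists lowest, but without such a gap, at most 19.1% against at least 20.5%. A bias toward GC-rich sequence was not tested and stays open here too. With 12540 peaks from each list the lowest share of the 6 stayed 9.26 points above the highest of the 3, which argues against list length. In the upper 50% of each list by score the gap was 9.16 points, so it did not come from the lower-scoring peaks within each list. Weak sites as such stay open, because the lists were selected by an unknown rule and scores cannot be compared between lists. The share of CTCF-overlapping peaks with centres within 50 bp was higher in all 6 lists, from 54.2% for HOXD9, than in the 3. It was 53.8% for HOXA11, 49.8% for HOXD11 and 33.9% for HOXD13. The intervals of HOXD9 (52.7 to 55.7) and HOXA11 (51.7 to 55.8) overlap. The random level was 1.34% against a CTCF share of 3.77% for HOXD13, and 1.42% against 16.7% for HOXD9. Chance overlaps, whose centres would spread evenly, thus weigh more in the 3 lists and lower their values. They were not removed, so this order cannot decide on open chromatin beside CTCF sites, which stays open. FLAG background at CTCF sites and recruitment of the HOX protein cannot be told apart, since CTCF-overlapping peaks had the lower median score percentile in 3 of the 6 lists and no FLAG control from cells without a tagged protein was used here.

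HOXA13 had the lowest mean Jaccard index with the other HOX lists, 0.133 against 0.197 for HOXD13, a gap of 0.394 of the whole range and within the limit for 9 values, and HOXD13 had the higher share of regions in no other list (33.4% against 31.9%). With equal list lengths the indices were 0.122 and 0.185, which argues against list length, and on chromosomes 1 to 5 alone 0.117 and 0.193, which argues against the microchromosomes. Of the strongest 10% of HOXA13 peaks 61.9% were in the HOXD13 list, 12.3 points below the median of 74.2% over the 64 ordered pairs that start from another list, a gap between the bounds set beforehand. For that same target the 7 other lists had a median of 63.6%, only 1.73 points higher, whereas for the 7 other targets HOXA13, with 47.5% to 65.4%, lay 11.3 to 28.7 points below their medians. It was below every other list for the targets HOXA9, HOXA11, HOXD9 and HOXD11. For HOXA10, HOXD10 and HOXD12 it lay within their range, with lowest values of 51.6%, 57.8% and 62.3%. False peaks from the single ChIP library and a distinct set of HOXA13 sites therefore cannot be told apart.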
